A study of Gallus gallus with 5 samples.

How the data were processed

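Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed for 2 histone arginine marks in nuclei of immature (polychromatic) chicken erythrocytes in G0. Per the labels' protocols, nuclei were fixed with 0.5% formaldehyde, the chromatin was sheared to fragments of 200 bp, and each mark was precipitated with its own antibody. The groups, taken from the labels, were H3R2me2s with 2 libraries, H4R3me2a with 2 libraries and input chromatin with 1 library. Replicate 1 of each mark was a SOLiD library, for which the labels' protocols give a size selection of 100 to 250 bp, and replicate 2 and the input were Illumina libraries. The series' design text calls the libraries of a mark biological replicates, and the labels do not say whether they came from separate animals.

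The authors deposited 1 peak list per library, and no list pooled libraries. Per the file headers, the replicate 1 lists were called with MACS 1.4.2 against a control at a p cutoff of 1e-05, with the local background taken over windows of 1 and 10 kb. Per the file headers, the replicate 2 and input lists were called with MACS 2.0.10.20120913 without a control at a q cutoff of 0.05, with a background window of 10 kb. Both versions kept 1 tag per position and used an effective genome size of 1e+09, per the file headers. Both replicate 1 lists were called against the same control library, which held 23.3 M tags after filtering, per the file headers. A like site in both lists may therefore owe part of its overlap to that control, and this part was not estimated because it needs the reads. Folder names in the replicate 1 headers hold the words lifescope and gal3. The headers of the Illumina lists name no genome build, and their aligner and build are not given in the sources used here. All 5 lists used the same chromosome names, and coordinates are given as the files hold them.

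The signal in the Illumina lists was the deposited pileup height at the summit, and the count in the SOLiD lists was the deposited number of tags in the peak. Fold enrichment over the local background, a ratio, was deposited for each peak in all lists. Significance was deposited as −log10 of the p-value and of the q-value in the Illumina lists, and as a score, 10 times the −log10 of the p-value, in the SOLiD lists, which also hold the false discovery rate in percent. These values per peak are the authors', and they were used only to describe, rank or filter peaks within a list. They were not compared as levels between lists, because platform, caller, control and depth all differed.

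The run names in the headers matched the labels of all 5 samples, but the numbers of the alignment files in the 3 Illumina headers differed from those in the labels. The header and label numbers were 11 and 10 for H3R2me2s replicate 2, 12 and 11 for H4R3me2a replicate 2, and 10 and 12 for the input. Samples kept the groups of their labels. The labels also name different breeds in different fields, so no breed is used here.

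Depth was read from the headers as tags after removal of repeated positions. It was 14.2 M for H3R2me2s replicate 1, 35.1 M for H3R2me2s replicate 2, 10.3 M for H4R3me2a replicate 1, 31.2 M for H4R3me2a replicate 2 and 27.1 M for the input. Wilson intervals at 95% are given for shares of peaks; they cover counting error only and treat peaks as independent, which neighbouring peaks are not.

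Before the data were examined, the tests, the alternatives and the rule for named regions were fixed. Peak lists were compared by the percent of peaks of the shorter list overlapped by at least 1 bp. Each overlap was set against 1000 random placements of the shorter list within its own chromosomes, which gave a mean, a fold and a 1-sided permutation p whose smallest possible value was 0.000999. The permutation was over peaks and not over biological samples, so p describes the pair of lists and not the spread between animals. The length of a chromosome was taken as the highest peak end in any list, called its spanned length, and gaps in the assembly were not masked, which raises the fold over random placement. Placement within 100 kb of each peak's own position was run beside it, since it keeps the regional density. Regions shared by the replicates of a mark were the bases covered by a peak in both. The Jaccard index was the number of bases covered by both lists over the number covered by either. Peak density was given in peaks per Mb for macrochromosomes (1 to 5), intermediate chromosomes (6 to 10), microchromosomes (11 and up) and Z. Relations between density and spanned length over autosomes above 1 Mb were tested with 100000 permutations of the chromosomes, 2-sided, with Benjamini-Hochberg adjustment over 8 relations. The microchromosome ratios of the marks were compared over libraries by 2-sided exact permutation, unpaired and within replicate number, which marks the platform; with 2 libraries per mark the smallest possible p was 0.333 unpaired and 0.5 in pairs, so neither can reach 0.05. This comparison was added after the data were seen. No other test across libraries was run, and single deviating libraries and other splits of the samples were not tested at this group size.

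The named regions were the 5 shared regions of each mark with the highest mean percentile of fold enrichment over its replicates. All other regions named by position, that is bins of 100 kb, chains of peaks with gaps of at most 3 kb, shared regions off input peaks and regions of a single mark, were chosen after their values were seen. The comparisons of Jaccard indices, bins, chains, summits, ranks and chromosome ends were also chosen after the data were examined. Promoter shares, 23 gene lists fixed beforehand, the comparison of marks over these lists and the named genes were not run, because the gene annotation at hand was of another build (GRCg7b) and the files pair no peaks with genes; coordinates were not converted. GC content was not checked for the same reason.

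The overlap functions were tested on simulated lists of 60000 peaks with the widths of the H4R3me2a and H3R2me2s replicate 1 peaks. With 0, 18.8 and 56.6% of peaks planted on a shared site, −0.0568, 17.9 and 55.2% were recovered above random placement. Alternatives covered the minimum overlap (50% of the shorter peak), the upper 50% of each list by fold enrichment, equal numbers of 77936 top peaks, removal of peaks on input peaks, local placement, leaving out each replicate and, added after the data were seen, a p-value of 1e-05 or lower in every list and other rankings. Alternative overlaps used 200 placements, with a smallest possible p of 0.00498. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.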

Results

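H3R2me2s, the symmetric dimethylation of arginine 2 of histone H3, and H4R3me2a, the asymmetric dimethylation of arginine 3 of histone H4, were mapped in immature chicken erythrocytes, nucleated red cells that no longer divide. H4R3me2a is laid down by PRMT1 and is known from active chromatin, and symmetric dimethylation of arginine is laid down by enzymes such as PRMT5. The data were 5 peak lists, 2 for each mark and 1 for input chromatin. H3R2me2s gave 103231 peaks in replicate 1 and 120536 in replicate 2, which covered 9.74 and 8.78% of the spanned genome. H4R3me2a gave 77936 peaks in replicate 1 and 113426 in replicate 2, which covered 8.33 and 6.02%. The input gave 10193 peaks over 0.206%. Median peak widths were 705 and 618 bp for H3R2me2s, 803 and 432 bp for H4R3me2a and 155 bp for the input. Replicate number went together with sequencing platform, depth, peak caller and use of a control, so replicates differed in all of these at once. The alignment file numbers in the headers and labels of the 3 Illumina libraries disagreed, so each statement on replicate 2 or the input rests on the labels.

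The replicates of each mark were compared to ask at which sites a mark was found in both libraries. Of the 103231 H3R2me2s peaks of replicate 1, 65.9% (95% interval 65.6 to 66.2) overlapped a peak of replicate 2. Of the 77936 H4R3me2a peaks of replicate 1, 68.5% (68.2 to 68.8) did. The H3R2me2s replicates shared 73377 regions of 46.0 Mb in all with a median width of 548 bp, and the H4R3me2a replicates shared 60689 regions of 32.4 Mb with a median width of 465 bp. Random placement within chromosomes gave 23.3 ± 0.126% (SD over placements) for H3R2me2s and 20.7 ± 0.136% for H4R3me2a. The observed shares were 2.83 and 3.31 times higher (1-sided permutation p = 0.000999 for both, the smallest these placements can give). Placement within 100 kb of each peak gave 32.3 and 28.7%, and folds of 2.04 and 2.39. Peaks are not biological replicates, and 2 libraries per mark on different platforms allow no test of the spread between animals.

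The marks were compared within each platform to ask whether they occupied the same sites. In replicate 1, 89.3% (89.1 to 89.5) of the H4R3me2a peaks overlapped an H3R2me2s peak. In replicate 2, 84.3% (84.1 to 84.5) of the H4R3me2a peaks did. Among regions shared by replicates, 78.2% (77.9 to 78.6) of the 60689 H4R3me2a regions overlapped an H3R2me2s region, and 49149 regions of 24.0 Mb carried both marks in both replicates. Random placement gave 25.9, 17.1 and 11.3% for these comparisons, so the folds were 3.45, 4.94 and 6.92 (1-sided permutation p = 0.000999 for each, the smallest possible). Seen from H3R2me2s, the longer list each time, the shares were lower. Of its peaks, 69.4% in replicate 1 and 73.8% in replicate 2 overlapped an H4R3me2a peak, and 62.8% of its shared regions overlapped an H4R3me2a region. Across platforms, 62.0% of H3R2me2s replicate 1 peaks overlapped an H4R3me2a replicate 2 peak and 69.5% of H4R3me2a replicate 1 peaks overlapped an H3R2me2s replicate 2 peak, folds of 3.22 and 2.79. The Jaccard index was 0.619 between the marks in replicate 1 and 0.540 in replicate 2, and it was lower between replicates of a mark, at 0.316 for H3R2me2s and 0.280 for H4R3me2a. Between different marks on different platforms it was 0.269 and 0.296. The size of the fold moved with the set of peaks: for the shared regions it was 3.45 without replicate 2, 4.94 without replicate 1, 4.44 with placement within 100 kb, 13.7 with equal numbers of top peaks and 19.9 in the upper 50% of each list, for replicate 2 it was 8.44 in the upper 50%, and for replicate 1 it was 2.19 with placement within 100 kb. For the shared regions the observed share fell as the fold rose, to 67.2% with equal numbers of top peaks and 51.9% in the upper 50%. Both replicate 1 lists used a single control library, so part of their overlap may come from it.

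**Figure D1:**
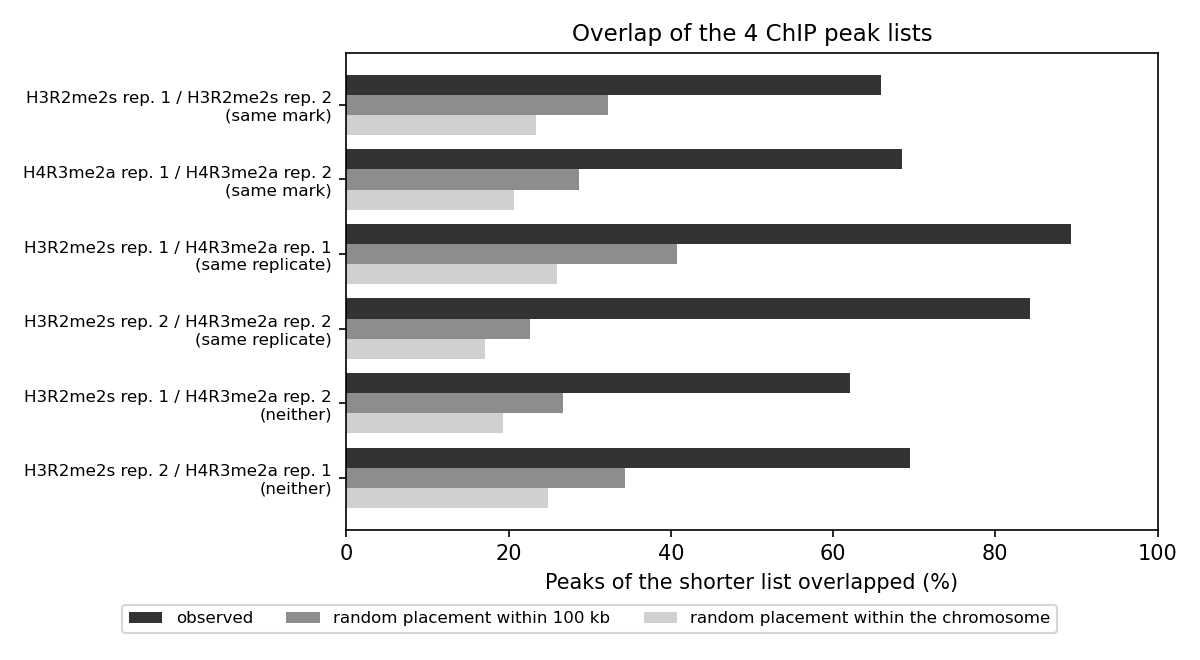
Percent of the peaks of the shorter list overlapped by at least 1 bp by the other list, for the 6 pairs of ChIP libraries. Dark bars show the observed share, mid-grey bars the mean of random placements within 100 kb and light bars the mean of random placements within the chromosome; the marks of 1 replicate overlapped at 89.3 and 84.3%, and the other pairs at 62.0 to 69.5%.

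Regions with both marks in all 4 lists covered 2.33% of the spanned genome and lay in most bins of 100 kb, with dense stretches on several small chromosomes. Of 10313 bins of 100 kb, 7869 (76.3%) held such a region, and 248 (2.40%) held no peak of any ChIP list. These shares of bins were not compared with random placement. The bin with the second highest cover by such regions was chromosome 18:9800001-9900000, where 36 regions covered 23.03% and input peaks covered 0.909%. Chromosome 13:10200001-10300000 (20.6%), chromosome 18:9700001-9800000 (19.9%), chromosome 26:4600001-4700000 (19.4%) and chromosome 11:19600001-19700000 (19.3%) were also among the 10 bins of highest cover, with input peaks on less than 1% of each. In the bin of highest cover, chromosome Z:71500001-71600000, input peaks covered 17.1%, and input cover was 9.36 to 25.3% in 4 further bins among the 10, on chromosomes Z, 6, 1 and 17. The longest chain of regions found in all 4 lists spanned 29.1 kb at chromosome 18:9838160-9867263 and held 14 regions. H3R2me2s peaks covered 64.1% of this chain in replicate 1 and 47.3% in replicate 2, H4R3me2a peaks covered 70.6 and 43.3%, and input peaks covered 1.21%. Chains at chromosome 23:5275916-5303801 (27.9 kb, 19 regions) and chromosome 15:10264542-10288487 (23.9 kb, 12 regions) followed, with 0 and 1 input peak. What genes lie there was not determined, because no annotation of the build was used here.

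**Figure D2:**
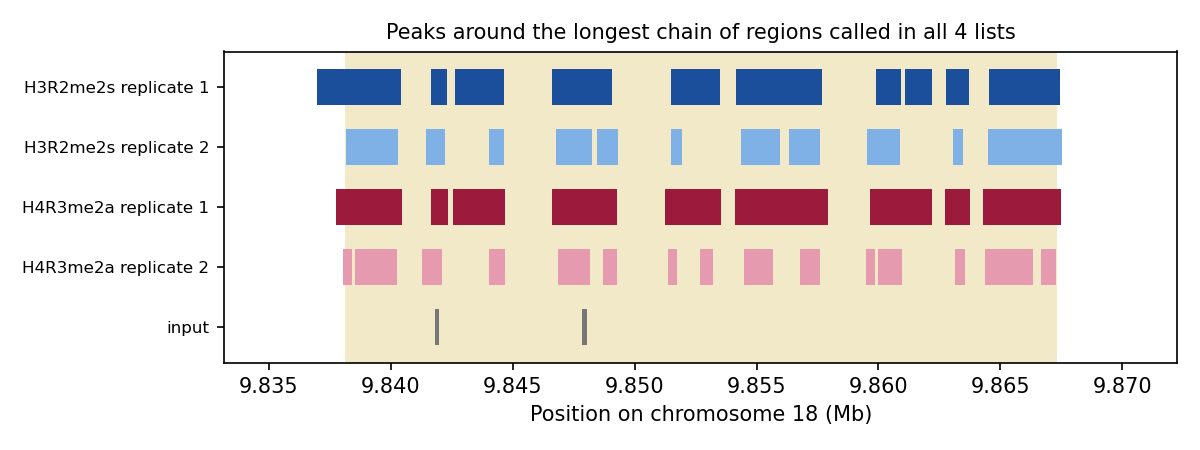
Map of chromosome 18 around the longest chain of regions called in all 4 ChIP lists (shaded, 9838160 to 9867263), with position in Mb on the horizontal axis and 1 track per library. Each block is a called peak drawn to scale; blocks of both marks recur at the same places in both replicates, and the input has 2 narrow peaks in the shaded part.

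Peaks in the replicate 1 lists ran together into long chains that the replicate 2 lists covered in part. The longest was at chromosome 4:517481-1194115, where 308 H3R2me2s peaks covered 76.7% of 676.6 kb and H4R3me2a peaks of replicate 1 covered 72.9%. In replicate 2, 193 H3R2me2s peaks covered 20.1% and 166 H4R3me2a peaks covered 10.96% of the same stretch, and the input had 1 peak there. Chromosome 26:204976-482964 was alike, with cover of 81.9 and 77.9% in replicate 1 and of 20.7 and 11.5% in replicate 2 for H3R2me2s and H4R3me2a. Chains of 5 or more peaks held 49.9% of H3R2me2s and 43.9% of H4R3me2a peaks in replicate 1, against 16.5 and 11.9% with random placement. In replicate 2 they held 14.2 and 12.2%, against 10.1 and 7.97%.

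The highest-ranked regions of each mark were named by the fixed rule. It averages ranks by fold enrichment, whose order over the regions in all 4 lists was inverse between replicates (mean Spearman rho −0.269). For H3R2me2s they were chromosome Z:61741622-61742490, chromosome 6:31463277-31464257, chromosome 9:9255425-9256077, chromosome 1:187202251-187203204 and chromosome 9:9256217-9256809. The deposited H3R2me2s fold enrichment at the Z region was 40.9 in replicate 1 and 14.3 in replicate 2, and at the chromosome 6 region it was 31.3 and 11.5. For H4R3me2a the regions were chromosome 9:9255556-9256853, chromosome 8:1179549-1180266, chromosome 5:59465308-59465884, chromosome 3:87207849-87208304 and chromosome 11:2146074-2146950. The deposited H4R3me2a fold enrichment at the chromosome 9 region was 53.0 in replicate 1 and 12.9 in replicate 2, and at the chromosome 11 region it was 39.0 and 11.7. All of these regions overlapped peaks of the other mark in both replicates. The 2 H3R2me2s regions on chromosome 9 lay on 1 peak of replicate 2 and overlapped the first H4R3me2a region, so they are not separate sites. Input peaks also lay on 4 of the 5 regions of each mark; the exceptions were the chromosome 6 region for H3R2me2s and the chromosome 11 region for H4R3me2a. Among regions off input peaks, those ranked next were chromosome 6:23415922-23417122 for H3R2me2s, with deposited folds of 25.3 and 9.52, and chromosome 1:7145526-7146423 for H4R3me2a, with 44.7 and 9.79.

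Input peaks gave the background measured in chromatin without antibody. They lay under 3.72% (3.61 to 3.84) of H3R2me2s replicate 1 peaks, 6.13% (6.0002 to 6.2711) of replicate 2 peaks, 5.16% (5.00 to 5.31) of H4R3me2a replicate 1 peaks and 6.63% (6.49 to 6.78) of replicate 2 peaks. These shares were 3.35, 6.80, 4.19 and 9.09 times those of random placement (1-sided permutation p = 0.000999 for each, the smallest possible). Of the regions shared by replicates, 5.44% of H3R2me2s and 7.12% of H4R3me2a regions overlapped an input peak, folds of 6.65 and 9.62. With placement within 100 kb these folds were lower, at 4.62 and 5.85. Those of the 4 lists, in the order above, were then 2.62, 5.14, 3.17 and 6.33. Seen from the input, 49.3% of its 10193 peaks were overlapped by H3R2me2s replicate 1, 89.3% by replicate 2, 52.3% by H4R3me2a replicate 1 and 87.6% by replicate 2. Among the 1000 peaks of highest fold enrichment, the share on input peaks was 24.6% (22.03 to 27.36) and 64.1% (61.1 to 67.0) for H3R2me2s replicates 1 and 2, and 26.3% (23.7 to 29.1) and 64.9% (61.9 to 67.8) for H4R3me2a. In the alternative with the upper 50% of each list, the input list was cut as well. The fold then rose to 11.8 and 15.8 for H3R2me2s and H4R3me2a in replicate 2 and to 12.4 and 15.3 for the shared regions. In replicate 1 it was 3.27 and 3.69, below the values of the whole lists. Because the input was cut too, these folds do not tell how often upper peaks lay on any input peak. Against all input peaks, the 1000 top peaks of replicate 1 had higher shares than the whole lists, at 24.6 against 3.72% for H3R2me2s and 26.3 against 5.16% for H4R3me2a. The longest input clusters were at chromosome Z:71554887-71624124 (67 peaks), chromosome Z:71820195-71876457 (46 peaks) and chromosome 17:515686-565314 (49 peaks), and H3R2me2s and H4R3me2a peaks covered 25.4 to 83.6% of each in every ChIP list.

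**Figure D3:**
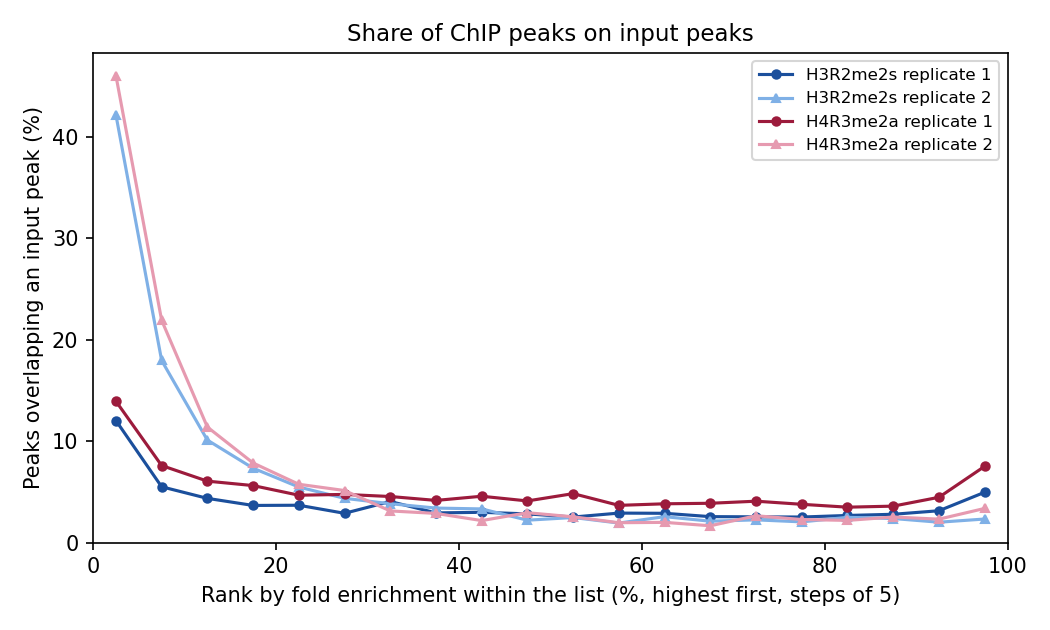
Percent of ChIP peaks that overlap an input peak (vertical axis) by rank of fold enrichment within the list (horizontal axis, steps of 5%, highest first), with circles for replicate 1 and triangles for replicate 2. Over whole lists the share was 3.72 to 6.63%, and it was highest among the top-ranked peaks of both replicate 2 lists.

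Both marks were denser on microchromosomes, the small gene-rich chromosomes of birds, than on macrochromosomes, and less dense on Z. H3R2me2s had 219 peaks per Mb on microchromosomes and 68.0 on macrochromosomes in replicate 1, a ratio of 3.22, and 195 and 99.9 in replicate 2, a ratio of 1.95. H4R3me2a had 173 and 49.1 in replicate 1, a ratio of 3.51, and 187 and 93.4 in replicate 2, a ratio of 2.01. The mean ratio was 2.58 ± 0.897 (SD, n = 2) for H3R2me2s and 2.76 ± 1.06 for H4R3me2a, where the SD holds the difference between platforms, and the input ratio was 1.24. Within each replicate the H4R3me2a ratio was higher, by 0.294 in replicate 1 and 0.0576 in replicate 2, a mean difference of 0.176 ± 0.167 (SD, n = 2 pairs). A 2-sided exact permutation within pairs gave p = 0.5, the smallest that 2 pairs allow, so a difference between the marks was neither shown nor excluded. For shared regions the ratios were 3.10 and 3.27. Relative to macrochromosomes, density on Z was 0.591 and 0.480 for H3R2me2s, 0.691 and 0.363 for H4R3me2a and 0.956 for the input. Intermediate chromosomes lay between, at 1.79 and 1.28 for H3R2me2s and 1.85 and 1.33 for H4R3me2a. Every list also held peaks on W, with 27 and 51 for H3R2me2s, 15 and 46 for H4R3me2a and 41 for the input. The sex of the animals and the number of Z copies were not taken into account. The lower density on Z is therefore one of called peaks, and whether the marks themselves were lower there was not tested. Among the 27 autosomes with a spanned length above 1 Mb, chromosome 26 was the densest in H3R2me2s replicate 1, with 342 peaks per Mb, and chromosome 2 the least dense, with 57.1. Over these 27 autosomes, density fell with the log10 of spanned length in all 4 ChIP lists, with Pearson r of −0.884 and −0.899 for H3R2me2s and −0.885 and −0.901 for H4R3me2a (permutation p = 1e-05 for each, the smallest possible, adjusted p = 1.1e-05). Spearman rho was −0.906, −0.927, −0.913 and −0.913 (permutation p = 1e-05 for each), and without chromosomes 1 and 2 Pearson r was −0.862, −0.895, −0.868 and −0.893. For the input r was −0.501 (permutation p = 0.007, adjusted p = 0.007), rho was −0.457 (permutation p = 0.017) and r without chromosomes 1 and 2 was −0.577. The ratio for shared regions depended on replicate 1: without replicate 1 it was 1.95 for H3R2me2s and 2.01 for H4R3me2a, and in the upper 50% of each list by fold it was 1.78 and 2.08.

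**Figure D4:**
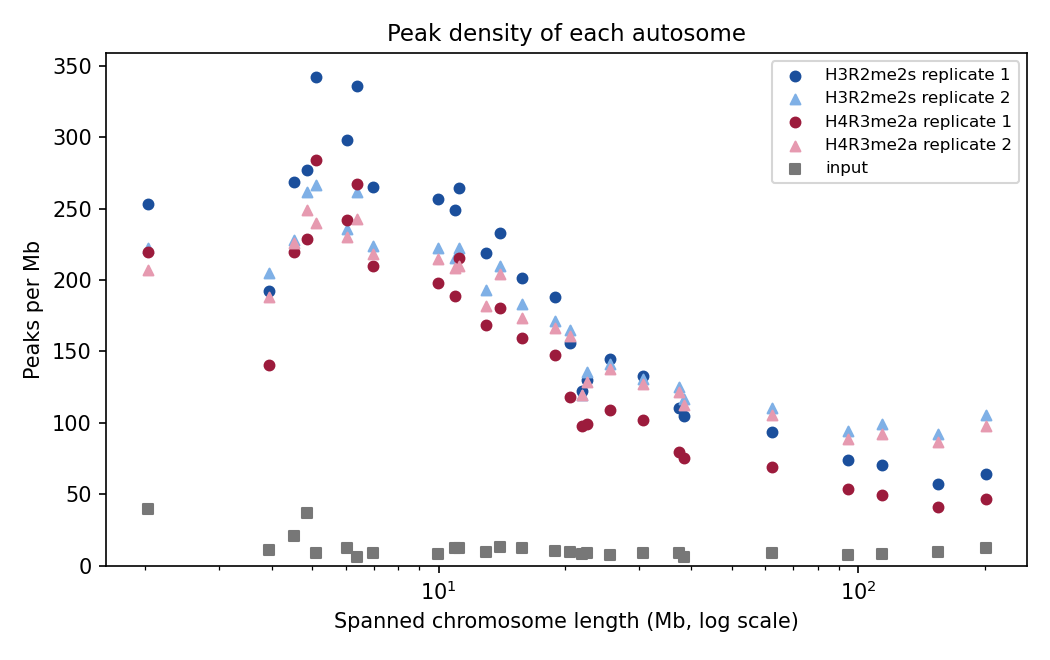
Peaks per Mb (vertical axis) against spanned chromosome length in Mb (horizontal axis, log scale) for 27 autosomes above 1 Mb, 1 point per chromosome and library. All 4 ChIP lists fall with length, with Pearson r between −0.884 and −0.901, and the input squares lie below the ChIP points of the same chromosome.

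Few shared regions carried 1 mark without any peak of the other. Of the 73377 H3R2me2s regions, 5031 or 6.86% (6.68 to 7.04) overlapped no H4R3me2a peak in either replicate, and of the 60689 H4R3me2a regions, 1409 or 2.32% (2.20 to 2.44) overlapped no H3R2me2s peak. This order depended on which peaks entered: with equal numbers of peaks from each list the shares were 5.60% for H3R2me2s and 6.64% for H4R3me2a ranked by fold, 5.50 and 5.97% by p-value and 12.4 and 14.6% with random draws, which turned the order, and 6.03 and 5.07% by pileup or tags, which did not. H3R2me2s regions without H4R3me2a were narrower than those with it in both replicates (median 391 against 617 bp) and more of them were on Z (6.54 against 2.00%). H4R3me2a regions without H3R2me2s were also narrower (291 against 510 bp), and 4.19 against 2.08% were on Z. A narrow region is less likely to touch a peak of the other mark at random, so some difference in width is built into this split. Width was not matched, and the number of Z copies was not taken into account. Lack of the other mark in replicate 1 and in replicate 2 went together, with an odds ratio within strata of rank of 1.36 (1.26 to 1.47, jackknife over chromosomes) for H3R2me2s regions and 1.78 (1.60 to 1.98) for H4R3me2a regions. With equal numbers of top peaks by fold these were 1.35 (1.23 to 1.47) and 1.06 (0.916 to 1.22), so for H4R3me2a the interval then included 1. The highest-ranked examples were chromosome 12:5887547-5888033 for H3R2me2s, with deposited folds of 14.4 and 7.32, and chromosome 6:9599192-9599621 for H4R3me2a, with 21.3 and 4.77. A peak missing from a list lay under that caller's threshold at that depth, which does not show that the mark was absent.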

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

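Of 73 alternative values computed, 26 were of settings added after the data were seen (the common p-value of 1e-05, other rankings, microchromosome density off input peaks, mark-only shares at equal numbers, and the replicate block). All 52 alternative overlaps, between replicates, between marks and with the input, stayed above random placement, with folds from 2.04 to 19.9 and permutation p under 0.05. The overlap shares depended more on the setting. In the upper 50% of each list, those between replicates fell from 65.9 to 31.6% for H3R2me2s and from 68.5 to 35.4% for H4R3me2a. Those between marks fell from 89.3 to 75.2% in replicate 1, from 84.3 to 76.3% in replicate 2 and from 78.2 to 51.9% in shared regions. Both lists of a pair were cut here, which leaves fewer peaks to be hit and lowers a share by itself. Leaving out a replicate gave a fold of 3.45 to 4.94 for the overlap of the marks, against 6.92 in shared regions, where the random share was 11.3% against 25.9 and 17.1%. Of 21 other alternatives, 9 kept their side of the threshold or moved by less than the replicate spread, and 12 moved by more or, for mark-only shares, left the 95% interval. In the upper 50% of each list the microchromosome ratio of shared regions was 1.78 for H3R2me2s and 2.08 for H4R3me2a, and leaving out a replicate gave 1.95 to 3.22 and 2.01 to 3.51; the lower value of each was without replicate 1, and the cause was not tested. With equal numbers of peaks, the H3R2me2s and H4R3me2a regions that lacked the other mark were 5.60 and 6.64% by fold, 5.50 and 5.97% by p-value, 12.4 and 14.6% with random draws and 6.03 and 5.07% by pileup or tags; all but the last turned the order of the marks, and the cause was not tested. Promoter shares, gene lists and their alternatives were not run, for lack of an annotation of the build. The replicate block applied to a single result, the difference of 0.176 in microchromosome ratio between the marks, with an exact permutation p of 0.5 in pairs and 0.667 unpaired; neither design can reach 0.05, so this says nothing about stability. The replicate 1 lists rested on 10.3 and 14.2 M tags, against 31.2 and 35.1 M in replicate 2, so a missing peak was read only as one below the threshold.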

Other observations

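The comparisons of chromosome ends, summits and rank orders were chosen after the data were seen, and the tests of explanations further on were written before their results were seen, except the random draws for the rotation of lists and the other rankings of equal numbers. On the 12 autosomes longer than 20 Mb, both marks were dense toward chromosome ends. Regions with both marks in all 4 lists had 119 per Mb between 0.1 and 0.5 Mb from an end and 116 between 0.5 and 1 Mb, 3.10 and 3.02 times the 38.4 per Mb over all positions. Between 5 and 10 Mb from an end they had 44.85 per Mb, 1.17 times. Each chromosome counted alike in these bands, but by its length over all positions, where long and less dense chromosomes weigh more. Part of each ChIP fold over all positions therefore comes from this weighting, and the bands are better compared with each other. H3R2me2s peaks at 0.5 to 1 Mb were at 3.37 times in replicate 1 and 1.95 in replicate 2, and H4R3me2a peaks at 3.60 and 1.99. Input peaks were at 1.60 times between 0.1 and 0.5 Mb and at 0.916 times between 0.5 and 1 Mb, but those in the outermost 0.1 Mb were at 7.78 times. Ends here are those of the spanned length, which need not be telomeres.

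Where peaks of both marks overlapped within a replicate, their summits lay close together. The median distance was 49 bp in replicate 1 and 91 bp in replicate 2, against 299 and 212 bp for random positions within the same peaks. Between replicates it was 161 bp for H3R2me2s, against 308, and 124 bp for H4R3me2a, against 287. Between different marks across replicates it was 141 bp for H3R2me2s replicate 1 with H4R3me2a replicate 2, against 270. For H4R3me2a replicate 1 with H3R2me2s replicate 2 it was 172 bp, against 332. The distances across replicates thus did not set own mark apart from other mark for H3R2me2s replicate 1. In the 49149 regions with both marks in all lists, the difference in rank between the marks was weakly shared by the platforms, with Spearman rho across regions of 0.136 (jackknife SE 0.0121) by fold enrichment and 0.262 (SE 0.0103) by pileup or tags. Regions are not independent replicates.

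The marks overlapped each other within a platform more than the replicates of a mark did, with a ratio of mean Jaccard indices of 1.94. With peaks on input peaks removed the ratio was 1.98. Only 3.72 to 6.63% of the peaks of each list lay on input peaks, so their removal could change the ratio little. The pattern thus held off called input peaks, and input signal below the calling threshold was not tested. With equal numbers of top peaks the ratio was 3.15 ranked by fold, 2.26 by p-value and 1.90 by pileup or tags. Its size depended on the ranking but stayed above 1, and platform and peak caller stay a candidate explanation. Each mark in replicate 1 overlapped the other mark in replicate 2 at 2.02 times or more the local random share, so the lists of the marks shared sites across platforms too. A location of both marks at the same sites could make the marks overlap as much as replicates of a mark do. It would not by itself make them overlap more, so it does not account for a ratio above 1. Replicate number followed platform, depth, caller and control together. The series calls the libraries of a mark biological replicates, so replicate number may also follow the chromatin sample. The shares of all these were not separated, and the antibodies' specificity was not tested.

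The alignment file numbers of the 3 Illumina lists differed between headers and labels, for a reason that stays open. For an exchange of the ChIP labels in replicate 2, the double ratio of Jaccard indices, own mark over other mark, was 1.11 (1.104 to 1.123, jackknife over chromosomes). This met the bound written beforehand against an exchange. The index also depends on the bases each list covers, which ran from 62.2 to 100.6 Mb over the ChIP lists. That part was not removed, so the ratio does not decide on an exchange. Its parts went opposite ways. H3R2me2s replicate 1 had an index of 0.316 with its own mark in replicate 2 and 0.269 with the other mark. For H4R3me2a replicate 1 these were 0.280 and 0.296. The folds over random placement for own and other mark also went opposite ways. They were 2.83 and 3.22 for H3R2me2s replicate 1, and 3.31 and 2.79 for H4R3me2a replicate 1. An exchange therefore stays open. A rotation of all 3 lists, with the list labelled H4R3me2a as the true input, met the bound written beforehand for it, with ratios of overlap folds of 1.004 and 1.041 ranked by fold and 1.244 by pileup for both, but that test is void, because under either ranking the top peaks of the list labelled H4R3me2a were rich in input sites (36.1 and 37.2% of the top 10000) and the overlap fold depends on peak width. With 10193 peaks of each list, drawn at random from the longer list, summits per 100 kb bin followed the replicate 1 cover of H3R2me2s and H4R3me2a at Spearman rho of 0.570 and 0.545 for the list labelled H4R3me2a and at 0.206 and 0.226 for the list labelled input. The smaller gap, −0.319 (jackknife SE 0.0271), argues against this rotation, although the share of summits inside replicate 1 peaks did not separate these lists (52.3 and 46.9% against 44.6 and 48.8%).

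The 1000 peaks of highest fold lay on input peaks more often in replicate 2 than in replicate 1, by 2.61 times for H3R2me2s and 2.47 times for H4R3me2a. The gap depended on ranking and number: by pileup or tags the shares in replicates 1 and 2 were 35.4 and 80.8% for H3R2me2s and 34.0 and 82.1% for H4R3me2a among 1000 peaks, but 93 and 98% and 96 and 98% among 100. For the top 1000 by fold, calling without a control, which keeps sites of high input signal, is a candidate explanation. Input peaks also overlapped the control-corrected replicate 1 peaks at 3.03 times or more the share of placement within 100 kb, so chromatin at marked sites may give more input fragments, and this stays open as well. Sites of high input signal in all libraries, such as collapsed repeats, were not tested because no sequence of the build was used here.

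Over the 49149 regions in all 4 lists, the order by deposited fold enrichment was inverse between replicates, with a mean Spearman rho over the marks of −0.269 (jackknife SE 0.0166). It was −0.302 in the 43646 regions not within 1 kb of an input peak and 0.243 (SE 0.0314) in the 1054 regions with no other ChIP peak within 10 kb. Some of the 49149 regions lie on the same peak and repeat its fold. In the 32595 regions that shared no peak with another region, rho was weaker, at −0.185 for H3R2me2s and −0.129 for H4R3me2a. Ranked by p-value over all 49149 regions, rho was near zero, at −0.0526 for H3R2me2s and −0.0106 for H4R3me2a. By pileup or tags rho was 0.520 for H3R2me2s and 0.589 for H4R3me2a. Between different marks it was 0.398 for H3R2me2s replicate 1 with H4R3me2a replicate 2. For H4R3me2a replicate 1 with H3R2me2s replicate 2 it was 0.616, so this agreement was not particular to a mark.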
